A study of Homo sapiens with 25 samples.

How the data were processed

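The data are 2 tables of gene counts, one for tumours and one for cultures, with 57820 genes in the same order. The deposited values are whole numbers, taken as raw counts per the labels, and no value contradicted that unit. The authors name FastQC, Trimmomatic, STAR, RSEM and the human genome build hg19, without versions. The counting itself was not repeated. Gene IDs were matched to GENCODE release 29, which holds 52338 of them, for gene type, chromosome and gene order. There were 29 gene symbols in the culture table that differed from the tumour table because they had turned into dates, and the tumour table's symbols were used.

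KO2 tumour 1 has counts on chromosomes 1 and 2 and the first part of chromosome 3 only, with 5117 genes above 0. The last gene with a count on chromosome 3 is UBA3. Chromosomes 1 and 2 hold 89.2% of its counts. It was left out before any test was run, which departs from the design, where all 16 tumours were to be used, and a fit with it was added as an alternative. The p-values measure the spread between these libraries, since nothing beyond the labels says that replicates are separate animals or separate cultures.

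Counts were fitted with edgeR 4.0.16 quasi-likelihood in R 4.3.3, with TMM scaling factors and the filterByExpr filter, and p-values were adjusted by the Benjamini and Hochberg method, with calls at an adjusted p under 0.05. The tumour fit held 15 libraries and 18226 genes, the culture fit 9 libraries and 16108 genes, and the fit of both sites 20 libraries (the parent tumours left out) and 18994 genes. Lines were weighted equally in each pooled comparison. Gene lists were written down before the data were examined, and were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and with an estimated correlation, 39 lists in tumours and 36 in culture, with lists of fewer than 5 measured genes left out. CPM values are counts scaled to the library total over the genes fitted times its TMM factor, set for tumours and cultures apart, log2 CPM values of genes use a prior count of 2 and list scores a prior count of 1. DESeq2 1.42.0 was the second tool. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

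Named genes are those set in the design: the 8 highest and 8 lowest protein-coding genes past the test with a mean log2 CPM of at least 3 for the main comparisons, 3 and 3 for comparisons between single lines, the key genes, and members of the gene lists. The text prints a part of them. LINC00920 lies outside that rule and was added after its values were seen. Fold changes of genes with a group at 0 are given as limits from 3 counts over the group.

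Pairs of replicate libraries had a chi-square per degree of freedom of 11.1 to 65.7 in tumours (21 pairs) and 3.65 to 20.7 in culture (9 pairs), where 1 is expected of counting noise alone. The alternatives were other scaling, no scaling, DESeq2, no filter and a stricter filter, a 2-fold minimum, each library left out, a cell content score as a covariate, only the 2 groups compared, the parent as control, the culture dates as blocks, an estimated correlation in camera and, added after the data were seen, the gene lists with each library left out and without MSLN as a member. No DNA data and no mouse reads were available, so human and mouse transcripts were not separated.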

Results

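Total RNA of KLM1, a human pancreatic cancer cell line, was sequenced to compare cells that carry mesothelin (MSLN), a cell surface glycoprotein, with clones edited to knock it out. The cells were sampled in culture and as tumours grown in the abdominal cavity of nude mice. The 25 libraries made 7 groups. Tumours came from the parent line, the control clone called mock and the knockout clones KO1 and KO2, with 4 libraries each. The parent line is labelled polyclonal, and mock, KO1 and KO2 are labelled monoclonal. Cultures came from mock, KO1 and KO2, with 3 libraries each. The parent line had no cultures. Parent tumours had 10654115, 14208080, 13643800 and 10415827 counts, mock tumours 11413022, 15473020, 12816969 and 9576434, and KO1 tumours 10767479, 12551231, 10945831 and 11322319. KO2 tumours 2, 3 and 4 had 10610540, 12013408 and 11740120 counts. KO2 tumour 1 had 2215814, none of them past the first part of chromosome 3, and was left out of every comparison. KO1 cultures had 19595399, 19121500 and 18556351 counts, KO2 cultures 16312908, 24617695 and 18590973, and mock cultures 19417611, 15934646 and 16095059.

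MSLN (ENSG00000102854.10, chromosome 16) was lower in both knockout clones than in mock and parent, in tumours and in culture, but its transcript was not absent. Its mean was 278 CPM (counts scaled to library size and TMM factor) in parent tumours (SD 41, n = 4), 211 in mock tumours (SD 59.1, n = 4), 31.2 in KO1 tumours (SD 6.09, n = 4) and 17.9 in KO2 tumours (SD 9.91, n = 3). In culture it was 111 in mock (SD 3.77, n = 3), 15.8 in KO1 (SD 1.36, n = 3) and 10.5 in KO2 (SD 0.794, n = 3). The log2 fold change of the knockout lines was -3.36 in tumours (SE 0.22, edgeR quasi-likelihood adjusted p = 1.49e-06) and -3.11 in culture (SE 0.066, adjusted p = 1.59e-12), and every knockout library lay below every MSLN-expressing library of its site. KO2 held less MSLN transcript than KO1 in culture (log2 fold change -0.59, SE 0.091, adjusted p = 0.000115). Parent and mock tumours differed by 0.40 on the log2 scale (adjusted p = 0.431), and mock, KO1 and KO2 tumours had more than the cultures (log2 fold change 0.79, SE 0.15, adjusted p = 0.000108). That last call was lost with the muscle and pancreatic acinar scores described further on as covariates (adjusted p = 0.102). Both scores are lower in every culture than in every tumour, so that fit cannot tell them from the site. The knockout difference in tumours minus that in culture was -0.05 (SE 0.32, adjusted p = 1).

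**Figure D1:**
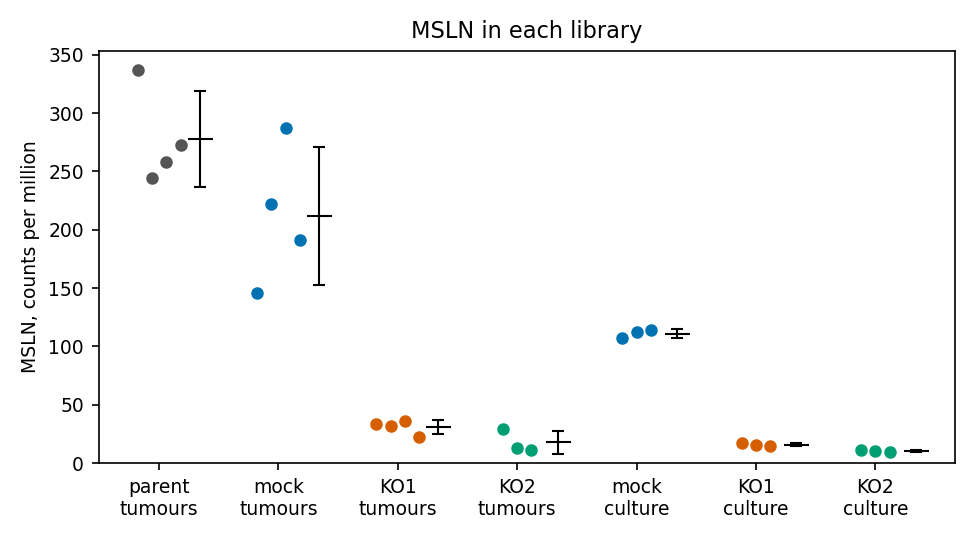
MSLN in CPM on the vertical axis for each library, with groups on the horizontal axis, points for libraries and bars for the mean with 1 SD. Knockout tumours lie between 11.6 and 36.4 and the other tumours between 146 and 337, while knockout cultures lie between 9.86 and 17.2 and mock cultures between 107 and 114.

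The comparison of knockout with MSLN-expressing tumours asked which genes differ in MSLN knockout tumours, with each line weighted equally. Interferon-stimulated genes were higher in the knockout tumours, but through KO1. OASL, an interferon-induced antiviral gene, had a mean of 74.1 CPM in KO1 tumours (SD 39.1, n = 4) against 6.43 in KO2 (SD 2.87, n = 3), 7.09 in mock (SD 2.36, n = 4) and 5.10 in parent tumours (SD 1.64, n = 4). CCL5, a chemokine that attracts T cells, was 17.9 CPM in KO1 (SD 6.85) and between 0.967 and 2.83 in the means of the other lines. Of 35 interferon-stimulated genes measured, 8 rose and none fell, 25 rose when adjusted over the list alone, and the median log2 fold change was 0.54 (camera adjusted p = 1.23e-25; adjusted p = 0.0386 with an estimated correlation). The 8 became 3 to 5 without parent tumour 1, 2 or 3, mock tumour 1, 2 or 3, KO1 tumour 3 or KO2 tumour 3, and 13 without KO1 tumour 4, while the list stayed called. OASL rose by 1.86 (SE 0.29, adjusted p = 0.00975), IFI44 by 1.72 (SE 0.26, adjusted p = 0.00936) and HERC5 by 1.28 (SE 0.23, adjusted p = 0.0186) on the log2 scale. CCL5 rose by 1.96 (SE 0.30, adjusted p = 0.00975).

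Other single genes past the test went both ways in knockout tumours. DUSP4, a phosphatase that switches off MAP kinases, fell by 0.60 (SE 0.11, adjusted p = 0.015), and lies in a block of chromosome 8 that was lower as a whole in KO1 than in mock (-0.52 in culture and -0.31 in tumours). EMP1, an epithelial membrane protein, fell by 0.91 (SE 0.17, adjusted p = 0.0226). COL17A1, a collagen of hemidesmosomes, fell by 0.74 (SE 0.14, adjusted p = 0.0194). MMP12, a matrix metalloproteinase, fell by 1.82 (SE 0.37, adjusted p = 0.0281). CST6, a protease inhibitor, rose by 1.83 (SE 0.34, adjusted p = 0.0204). SPRR1B, a protein of the cornified envelope, rose by 1.85 (SE 0.38, adjusted p = 0.0281), and ERBB2, a receptor tyrosine kinase, rose by 0.56 (SE 0.11, adjusted p = 0.0278). ERBB2 had a mean of 603 CPM in KO2 tumours and of 232 to 339 in the other lines, so the pooled values can come from 1 clone. Epithelial genes had a median of -0.12, with 0 of 25 past the test over all genes or over the list alone (camera adjusted p = 0.00683; adjusted p = 0.267 with an estimated correlation), and 1 lower without parent tumour 4 or KO2 tumour 2. Genes of MAPK pathway output had a median of 0.03 but a mean of -0.07 and a camera direction of down, with 2 of 18 lower over all genes and 4 when adjusted over the list alone (camera adjusted p = 0.135). Of 33 hypoxia response genes, none passed over all genes, 13 were lower when adjusted over the list alone, and the median was -0.34 (camera adjusted p = 2.17e-10; adjusted p = 0.252 with an estimated correlation). Without KO2 tumour 4, 5 of them were lower over all genes, and 1 without KO1 tumour 4 or mock tumour 4. The 15 genes measured beside MSLN had a median of -0.47, with METRN (-1.02, adjusted p = 0.0271) and JMJD8 (-0.48, adjusted p = 0.0286) lower and 9 lower when adjusted over the list alone (camera adjusted p = 1.1e-08; adjusted p = 0.0961 with an estimated correlation). The 2 became 1 without parent tumour 1 or 2 or KO1 tumour 2 or 3, and 0 without parent tumour 3, mock tumour 3 or KO2 tumour 3 or 4. Macrophage markers had a median of 0.65 and fibroblast markers of 0.47 with no member past the test over all genes, 9 of 16 and 2 of 18 higher when adjusted over the list alone, and camera adjusted p of 2.99e-08 and 1.06e-07 (adjusted p = 0.0961 and adjusted p = 0.267 with an estimated correlation). Over all genes 1 macrophage marker was higher without mock tumour 4, and 1 fibroblast marker without parent tumour 4. The mean log2 CPM of the fibroblast markers was 5.09 in parent, 5.73 in mock, 5.84 in KO1 and 6.03 in KO2 tumours. Their pooled rise can therefore come through low parent tumours.

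Among the key genes of tumour growth and spread, only MSLN passed this test. VEGFA, the main growth factor of blood vessels, had a log2 fold change of -0.54 (SE 0.25, adjusted p = 0.357), MMP7 of -0.91 (SE 0.31, adjusted p = 0.187), MUC16, the mucin that binds MSLN, of -0.36 (SE 0.15, adjusted p = 0.299), and ICAM1 of 0.14 (SE 0.15, adjusted p = 0.714). Of 26 angiogenic factors none passed over all genes, 1 was higher and 1 lower when adjusted over the list alone, and the median was -0.07 (camera adjusted p = 0.418). In all, 177 of 18226 genes passed the edgeR quasi-likelihood test, 66 higher and 111 lower. The other ways to pair the lines gave more, 360 for KO1 and mock against KO2 and parent and 742 for KO1 and parent against KO2 and mock. The last pairing largely follows the pancreatic acinar markers described further on, which were high in KO1 tumours and most parent tumours. Camera called 15 of 39 lists, and 2 of them with an estimated correlation (the interferon-stimulated genes and the key genes, the latter at adjusted p = 3.42e-06 and adjusted p = 0.0152 with an estimated correlation). The key genes hold MSLN itself, and without it they had a median of -0.23 with 0 of 12 past the test over all genes or over the list alone (camera adjusted p = 0.0346; adjusted p = 0.271 with an estimated correlation). The count was 3 with a score of blood vessel, fibroblast, macrophage and red cell markers as a covariate, 66 with the muscle and acinar scores as covariates and 626 with DESeq2. It was between 66 and 114 when parent tumour 1, 2 or 3, KO1 tumour 2 or 3, mock tumour 1, 2 or 3 or KO2 tumour 3 or 4 was left out. MSLN, OASL, IFI44, HERC5, CCL5 and DUSP4 kept their calls without any single tumour, unlike each other named gene past the test, and with the cell content score all of these but MSLN lost them. The log2 fold changes with that score were 1.99 for OASL (adjusted p = 0.109), 2.31 for CCL5 (adjusted p = 0.0701), 1.71 for IFI44 (adjusted p = 0.164), 1.32 for HERC5 (adjusted p = 0.265) and -0.51 for DUSP4 (adjusted p = 0.388).

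KO1 tumours, compared with mock, had high digestive enzyme transcripts and high interferon-stimulated genes. Of 14 pancreatic acinar markers 12 rose over all genes and over the list alone (camera adjusted p = 4.4e-30; adjusted p = 0.062 with an estimated correlation). AMY2B, an amylase, had a mean of 549 CPM in KO1 (SD 298, n = 4) and 2.39 in mock (SD 1.09, n = 4), and CELA1, an elastase, had 295 (SD 204) and 1.22 (SD 0.242). Of 35 interferon-stimulated genes 21 rose, and 31 when adjusted over the list alone, with a median of 1.29 (camera adjusted p = 3.86e-57; adjusted p = 0.00456 with an estimated correlation). Cholesterol synthesis genes were lower, 3 of 23 over all genes and 15 when adjusted over the list alone, with a median of -0.58 (camera adjusted p = 3.52e-12; adjusted p = 0.158 with an estimated correlation), and the 3 became 1 without KO1 tumour 2 or 4 or mock tumour 3. Markers of other cell types moved too. Macrophage markers had a median of 0.71 with 0 of 16 past the test over all genes or over the list alone (camera adjusted p = 1.54e-05; adjusted p = 0.199 with an estimated correlation), and 1 higher over all genes without mock tumour 4. Muscle markers had a median of -2.08 with 0 of 13 past either test (camera adjusted p = 0.000389; adjusted p = 0.635 with an estimated correlation), which was -7.43 without KO1 tumour 1 and -1.38 without mock tumour 4. Mitochondrial transcripts had a median of 0.34 (camera adjusted p = 0.0112), a call lost without KO1 tumour 3 (median 0.14, adjusted p = 0.278). RBM3, a cold-induced RNA-binding protein on the X chromosome, fell by 1.90 (SE 0.35, adjusted p = 0.00906). In total 302 genes passed, 176 higher and 126 lower. With the muscle and acinar scores as covariates edgeR called 0, with 710 at an unadjusted p under 0.05, and MSLN itself was then at -2.68 (SE 0.56, adjusted p = 0.577). DESeq2, run without these scores, gave 787, and leaving out KO1 tumour 2 or 4 or mock tumour 1, 2 or 3 gave 141 to 195.

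KO2 tumours, compared with mock, had higher KRT10 and SPINK5, of which KRT10 lies in a block of chromosome 17 that was higher as a whole. KRT10, a keratin of the upper skin layers, rose by 2.43 (SE 0.35, adjusted p = 0.00411), from a mean of 71.5 CPM in mock (SD 19.5, n = 4) to 385 in KO2 (SD 181, n = 3). SPINK5, a protease inhibitor of skin, rose by 2.50 (SE 0.35, adjusted p = 0.00411), from 36.3 CPM (SD 8.43) to 205 (SD 71.5). Of the genes beside MSLN 3 of 15 fell, among them HAGHL (-1.32, SE 0.27, adjusted p = 0.041), and 7 were lower and 1 higher when adjusted over the list alone (median -0.68, camera adjusted p = 1.76e-07; adjusted p = 0.238 with an estimated correlation). The 3 became 0 without mock tumour 1, 2, 3 or 4 or KO2 tumour 3 or 4, and 5 without KO2 tumour 2. The interferon-stimulated genes had a median of 0.08 with none past the test over all genes or over the list alone (camera adjusted p = 0.4). Genes of MHC class I antigen presentation had a median of -0.35, with 0 of 15 past the test over all genes and 2 lower when adjusted over the list alone (camera adjusted p = 4.44e-05; adjusted p = 0.238 with an estimated correlation), and a median of -0.53 without KO2 tumour 2. Macrophage markers had a median of 0.39 with 0 of 16 past the test over all genes or over the list alone (camera adjusted p = 0.0334; adjusted p = 0.548 with an estimated correlation). That call was lost without mock tumour 2 (adjusted p = 0.14) or 3 (adjusted p = 0.0783) or KO2 tumour 2 (adjusted p = 0.0603) or 3 (median 0.10, adjusted p = 0.681). Fibroblast markers had a median of 0.35 with 0 of 18 past either test (camera adjusted p = 0.0446; adjusted p = 0.714 with an estimated correlation). That call was lost without mock tumour 2 (adjusted p = 0.0526) or 3 (adjusted p = 0.149) or KO2 tumour 2 (adjusted p = 0.13), 3 (median 0.21, adjusted p = 0.0623) or 4 (adjusted p = 0.0937). Housekeeping genes had a median of -0.16 with 0 of 14 past either test (camera adjusted p = 0.0364; adjusted p = 0.434 with an estimated correlation), and -0.27 without KO2 tumour 4. Their call was lost without mock tumour 2 (adjusted p = 0.0611) or 3 (adjusted p = 0.104) or KO2 tumour 2 (adjusted p = 0.0602) or 3 (median -0.10, adjusted p = 0.22). In total 78 genes passed, 43 higher and 35 lower. The count was 331 with DESeq2, 2 when only mock and KO2 tumours were fitted and 46 with the cell content score. Leaving out mock tumour 1, 2 or 3 or KO2 tumour 2, 3 or 4 gave 36, 43, 38, 135, 17 and 39.

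Parent and mock tumours, which both express MSLN, differed as much as these pairs. The parent is polyclonal and mock monoclonal, so this comparison also sets a mixed line against a single clone. Parent tumours had more mucins, 3 of 11 over all genes and 8 when adjusted over the list alone (median 1.27, camera adjusted p = 4.42e-09; adjusted p = 0.117 with an estimated correlation). They had more genes of the classical pancreatic cancer subtype, 5 of 17 and 7 when adjusted over the list alone (median 0.93, camera adjusted p = 3.82e-06; adjusted p = 0.242 with an estimated correlation). Proliferation genes had a median of -0.53, with 2 of 36 lower over all genes and 22 when adjusted over the list alone (camera adjusted p = 6.08e-14; adjusted p = 0.43 with an estimated correlation). Fibroblast markers had a median of -0.56, with 0 of 18 past the test over all genes and 3 lower when adjusted over the list alone (camera adjusted p = 9.26e-05; adjusted p = 0.63 with an estimated correlation), so cell content moves with these lists. That median was -0.32 without parent tumour 1, and 2 fibroblast markers were lower over all genes without parent tumour 4. Over all genes, the 2 proliferation genes became 8 without parent tumour 4 and 0 without parent tumour 1, 2 or 3 or mock tumour 1, 2 or 3. The 3 mucins became 5 without parent tumour 4, and the 5 classical genes 1 to 3 without parent tumour 1, 2 or 3 or any mock tumour. IL1A, an inflammatory cytokine, fell by 2.20 (SE 0.49, adjusted p = 0.0271). FABP4, a fatty acid carrier of fat cells, fell by 2.39 (SE 0.55, adjusted p = 0.0303). Adipocyte markers had a median of -1.67 (camera adjusted p = 0.0138), and -0.51 without mock tumour 3 (adjusted p = 0.0675). Muscle markers had a median of -1.01 (camera adjusted p = 0.0274), and -7.94 without parent tumour 4. Mitochondrial transcripts had a median of 0.34 (camera adjusted p = 0.0492). The muscle and mitochondrial calls were each lost in 4 of 8 fits with a library left out. Acinar markers were high in parent tumours 1, 2 and 3 and low in mock, and 13 of 14 rose over all genes and over the list alone (camera adjusted p = 2.66e-17; adjusted p = 0.222 with an estimated correlation). Of 541 genes past the test 412 were higher and 129 lower. The count was 9 with the cell content score, 1 with the muscle and acinar scores and 1415 with DESeq2. Leaving out parent tumour 1, 2, 3 or 4 or mock tumour 1, 2 or 3 gave 86, 165, 286, 855, 137, 245 and 245.

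The knockout clones differed from each other in tumours, although both are MSLN knockouts. KO2 tumours had less of the interferon-stimulated genes, 20 of 35 over all genes and 29 when adjusted over the list alone (median -1.23, camera adjusted p = 3.61e-36; adjusted p = 0.0264 with an estimated correlation). They had less of MHC class I antigen presentation, 4 of 15 and 11 when adjusted over the list alone (median -0.74, camera adjusted p = 4.9e-09; adjusted p = 0.0544 with an estimated correlation). The 20 became 10 and 13 without KO2 tumour 3 or 4, and the 4 became 2 without KO1 tumour 1 or 2, 0 without KO2 tumour 3 and 1 without KO2 tumour 4. KRT1, a keratin of the upper skin layers, rose by 4.82 (SE 0.78, adjusted p = 0.0048). SCGB1A1, a secretory protein of airway club cells, rose by 2.80 (SE 0.49, adjusted p = 0.00701), from a mean of 101 CPM in KO1 (SD 41.3, n = 4) to 701 in KO2 (SD 439, n = 3). Of the acinar markers 12 of 14 fell, and 13 when adjusted over the list alone (camera adjusted p = 5.49e-23; adjusted p = 0.0544 with an estimated correlation). Muscle markers had a median of 3.25 with 0 of 13 past the test over all genes or over the list alone (camera adjusted p = 1.39e-05; adjusted p = 0.468 with an estimated correlation), which was 8.71 without KO1 tumour 1 and 2.07 without KO2 tumour 3. Of 546 genes past the test 291 were higher and 255 lower. With the muscle and acinar scores as covariates edgeR called 0, with 1114 at an unadjusted p under 0.05, while DESeq2 without them gave 1159. Leaving out KO1 tumour 2 or KO2 tumour 3 or 4 gave 240, 242 and 265.

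Markers of muscle and of pancreatic acinar cells set tumours apart within and between lines. The muscle score, a mean log2 CPM over the list, was 0.03 to 8.38 in parent, 0.38 to 7.30 in KO1, 1.64 to 8.47 in mock and 6.10 to 9.66 in KO2 tumours, and at most -1.52 in culture. The acinar score was 3.19 or more in every KO1 tumour and in parent tumours 1, 2 and 3, and -1.39 or less in the others. ACTA1, the actin of skeletal muscle, ranged from 4.88 to 5020 CPM among tumours and stayed at or below 0.431 in culture. CTRB2, a digestive protease, reached 1110 CPM in a KO1 tumour and 1.00 at most in mock tumours.

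**Figure D2:**
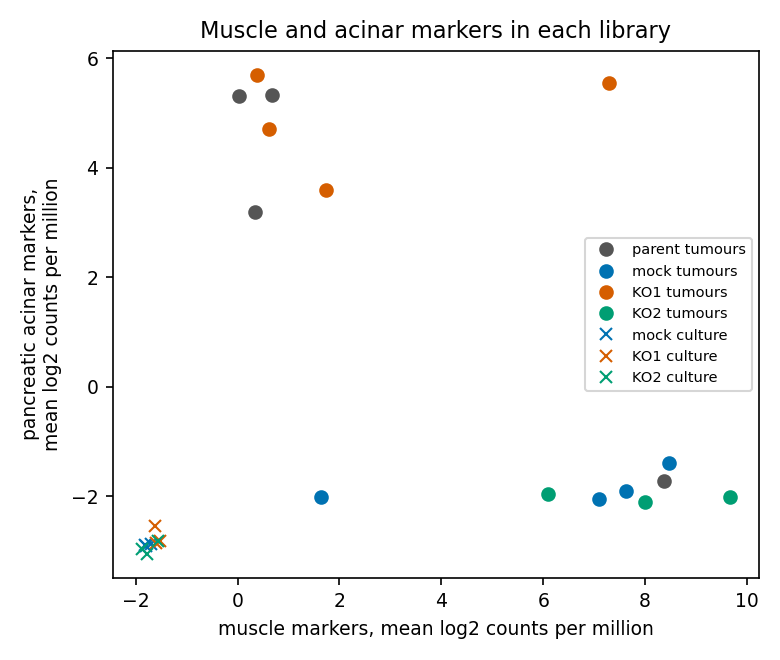
Muscle marker score against pancreatic acinar marker score, both in mean log2 CPM, with a circle for each tumour and a cross for each culture, coloured by line. There are 8 tumours with a muscle score of at least 6.10 and 7 with an acinar score of at least 3.19, and all cultures lie at the lower left.

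The knockout lines shared few calls of single genes in tumours that held against both controls. Only 2 genes passed edgeR's test with the same sign for each knockout line against each of mock and parent, both lower: MSLN and the long noncoding RNA LINC00920, which was named after its values were seen (pooled log2 fold change -1.41, SE 0.17, adjusted p = 0.0017). At an unadjusted p under 0.05 in every pair there were 75 such genes, and DESeq2 gave 8. Across genes, which are not independent replicates, the tumour differences of KO1 and KO2 from mock had a correlation of 0.13 where unchanged simulated groups with a shared control gave 0.45 (covariance 0.042 against 0.068, same sign in 59.9% against 65%), and with mock tumours split between the clones it was -0.04. Against mock 5 genes were higher and 2 lower in both clones, where independent calls would share 0.415 and 0.242. Against parent 19 were higher and 96 lower in both, where independent calls would share 2.87 and 8.44, and the correlation was 0.37 against 0.46 in unchanged simulated groups (covariance 0.168 against 0.069, same sign in 69% against 65.3%). Both clones share the control in each of these, and 0 genes were called in opposite ways. With different controls the correlation was -0.43 for KO1 against mock and KO2 against parent, with 0 genes higher and 5 lower in both and 39 opposite. It was -0.08 for KO1 against parent and KO2 against mock, with 1 higher, 2 lower and 7 opposite. The difference of KO1 from mock correlated between tumours and culture at 0.38, and that of KO2 at 0.37. Across clones it was 0.21 for KO1 tumours and KO2 cultures and -0.11 for KO2 tumours and KO1 cultures. The count was 1 without KO2 tumour 3, 1 with the cell content score, 1 with a stricter filter and 0 with the muscle and acinar scores, where 7 had an unadjusted p under 0.05 in every pair.

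The culture comparison asked the same question in cells grown without a host. Mock was the only control clone, so the knockout cannot be told apart from traits of mock itself. The p-values measure the spread between libraries of a clone, not between clones. Genes called the same way against both other lines numbered 1035 for mock, 4452 for KO1 and 2738 for KO2. The mucin gene MUC4 and ICAM1 were among the genes higher in the knockout clones, and GJA1, BMP7 and COL6A1 among the lower ones. MUC4, a membrane mucin, rose from 23.7 CPM in mock (SD 8.56, n = 3) to 88.2 in KO1 (SD 13.1, n = 3) and 93.0 in KO2 (SD 5.44, n = 3), a log2 fold change of 1.94 (SE 0.16, adjusted p = 4.15e-06). ICAM1, an adhesion molecule for leukocytes, rose from 23 CPM in mock (SD 0.983) to 46.5 in KO1 (SD 0.443) and 34.4 in KO2 (SD 0.866), a log2 fold change of 0.79 (SE 0.062, adjusted p = 2.64e-06). GJA1, the gap junction protein connexin 43, fell by 1.60 (SE 0.13, adjusted p = 2.64e-06). BMP7, a growth factor of the TGF-beta family, fell by 1.45 (SE 0.11, adjusted p = 2.63e-06), and COL6A1, a collagen, fell by 1.56 (SE 0.16, adjusted p = 2.73e-05).

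Of the mucins measured in culture 5 of 7 rose over all genes and over the list alone (median 0.58, camera adjusted p = 0.000197; adjusted p = 0.144 with an estimated correlation), with MUC20 at 0.59 and MUC1 at 0.58. Of the interferon-stimulated genes 23 of 35 rose, and 27 when adjusted over the list alone (median 0.61, camera adjusted p = 1.94e-11; adjusted p = 0.497 with an estimated correlation). Of the NF-kB targets 6 of 21 rose, among them LCN2, an iron-binding defence protein (1.82, SE 0.20, adjusted p = 3.62e-05), and 7 when adjusted over the list alone (median 0.36, camera adjusted p = 0.000197; adjusted p = 0.23 with an estimated correlation), with a median of 0.22 without KO2 culture 1. Of MHC class I antigen presentation 9 of 15 rose and 2 fell, over all genes and over the list alone (median 0.37, camera adjusted p = 0.00112; adjusted p = 0.309 with an estimated correlation), with PSMB9 at 0.70 and ERAP2 at -0.44. Of the cholesterol synthesis genes 7 of 23 fell over all genes and over the list alone (median -0.19, camera adjusted p = 0.00233; adjusted p = 0.64 with an estimated correlation), with EBP at -0.83. Of the 15 genes beside MSLN 7 fell and 1 rose, and 8 and 1 when adjusted over the list alone (median -0.46, camera adjusted p = 0.000464; adjusted p = 0.194 with an estimated correlation). Of the apoptosis regulators 6 of 27 rose over all genes and over the list alone (median 0.12, camera adjusted p = 0.0241; adjusted p = 0.194 with an estimated correlation), among them BMF (0.73) and PMAIP1 (0.40), which promote cell death, and BCL2L1 (0.29), which counters it. Without mock culture 1, 2 or 3 the 23 interferon-stimulated genes became 12, 11 and 15, and the 6 apoptosis regulators became 3 without mock culture 1 or 2. Without mock culture 1 the 5 mucins and the 6 NF-kB targets became 3 each, and of MHC class I 7 rose and 1 fell. Mitochondrial transcripts had a median of 0.41 (camera adjusted p = 0.00112), and 0.18 without mock culture 3 (adjusted p = 0.0413). They were not called with an estimated correlation. The 7 cholesterol synthesis genes became 12 without KO2 culture 1, and 1 apoptosis regulator fell without KO1 culture 3. The mucin rise in culture is against mock alone. In tumours the mucins were higher in KO1 than in mock (median 0.62, camera adjusted p = 0.000125). Against parent tumours they were lower in KO1 (median -0.58, adjusted p = 0.0457) and in KO2 (median -1.12, adjusted p = 1.2e-06). That KO1 call was lost in 4 of 8 fits with a library left out.

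These pooled culture values came through different clones. The NF-kB targets were called as a list in KO1 at the preset correlation, though not with an estimated one. In KO2 they were not called, since 4 of 21 rose and 5 fell over all genes and over the list alone (median -0.17, camera adjusted p = 0.938). Cholesterol synthesis genes fell in KO1, 14 of 23 and 15 when adjusted over the list alone (median -0.33, camera adjusted p = 1.25e-05; adjusted p = 0.51 with an estimated correlation), and 8 without mock culture 1. In KO2 2 rose and 2 fell, and 2 and 1 when adjusted over the list alone (median -0.01, camera adjusted p = 0.956). Of the apoptosis regulators 12 of 27 rose and 1 fell in KO1, likewise over the list alone (median 0.13, camera adjusted p = 0.034; adjusted p = 0.258 with an estimated correlation). That call was lost without KO1 culture 3 (adjusted p = 0.0638), and 7 rose without KO1 culture 1 or mock culture 1. In KO2 5 rose and 1 fell, likewise over the list alone (median 0.04, camera adjusted p = 0.385). The mucins had 2 of 7 higher in KO1, likewise over the list alone (median 0.17, camera adjusted p = 0.229). Of MHC class I antigen presentation 7 of 15 rose and 2 fell in KO1, likewise over the list alone (median 0.23, camera adjusted p = 0.307). In KO2 9 rose and 1 fell, and 11 and 1 when adjusted over the list alone (median 0.39, camera adjusted p = 5.78e-05; adjusted p = 0.321 with an estimated correlation). Of the 15 genes beside MSLN 1 rose and 4 fell in KO1, and 1 and 6 when adjusted over the list alone (median -0.23, camera adjusted p = 0.201). In KO2 2 rose and 8 fell over all genes and over the list alone (median -0.63, camera adjusted p = 5.78e-05; adjusted p = 0.222 with an estimated correlation).

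Among the other key genes in culture, MMP7 rose by 0.89 (SE 0.15, adjusted p = 0.00102), MMP9 fell by 0.85 (SE 0.19, adjusted p = 0.00533) and CDH1, the adhesion protein of epithelia, fell by 0.22 (SE 0.059, adjusted p = 0.0162). VEGFA had a log2 fold change of -0.12 (SE 0.082, adjusted p = 0.345) and MYC of -0.04 (SE 0.087, adjusted p = 0.812). INSR, the insulin receptor, fell by 1.68 (SE 0.16, adjusted p = 8.55e-06). APCDD1, an inhibitor of WNT signalling, fell by 2.61 (SE 0.28, adjusted p = 3.28e-05). In all 3527 of 16108 genes passed, 1689 higher and 1838 lower, and 1130 and 2668 with no scaling factors. Leaving out mock culture 1, 2 or 3 gave 2126, 2220 and 2223 genes, 398 had at least a 2-fold change, and a fit with the dates in the sample titles as blocks gave 4577.

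Each clone against mock in culture showed mostly its own changes. In KO1 the interferon-stimulated genes rose in 29 of 35, and 31 when adjusted over the list alone (median 1.07, camera adjusted p = 3.43e-12; adjusted p = 0.51 with an estimated correlation), with a median of 0.53 without KO1 culture 2. NF-kB targets rose in 15 of 21 over all genes and over the list alone (median 0.94, camera adjusted p = 7.44e-09; adjusted p = 0.258 with an estimated correlation). In KO2 the mucins rose in 5 of 7 over all genes and over the list alone (median 0.68, camera adjusted p = 2.54e-06; adjusted p = 0.0286 with an estimated correlation). There 8 of 35 interferon-stimulated genes rose over all genes and over the list alone (median 0.15, camera adjusted p = 0.0187; adjusted p = 0.85 with an estimated correlation), and that call was lost without mock culture 2 (median 0.04, adjusted p = 0.0713). PLXDC2, a transmembrane protein, rose in KO1 by 3.06 (SE 0.14, adjusted p = 1.82e-08) and lies in a block of chromosome 10 at 0.49 there, and HCLS1, a cytoskeletal adaptor of blood cells, fell by 3.55 (SE 0.16, adjusted p = 1.36e-08). In KO2 CXXC5, a zinc finger protein, rose by 2.14 (SE 0.17, adjusted p = 2.5e-06) and the chemokine CX3CL1 fell by 2.29 (SE 0.19, adjusted p = 2.39e-06). KO1 had 6070 genes past the test, 3184 higher and 2886 lower, or 2253 and 3775 with no scaling factors, and KO2 had 4014, 1886 higher and 2128 lower, or 1451 and 2642 with no scaling factors. Both clones rose in 547 genes and fell in 488, where independent calls would share 373 and 381 and both clones share the mock control, and 827 genes went opposite ways. Over all genes 51.3% had the same sign in both clones, against 67% in unchanged simulated groups with a shared control. The correlation was 0.12 against 0.51, and the covariance 0.035 against 0.019. At 2-fold or more the counts were 1051 for KO1 and 620 for KO2, and with the dates as blocks 6963 and 4974.

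Between the cultured knockout clones, KO2 had less of the NF-kB targets, 15 of 21 over all genes and 16 when adjusted over the list alone (median -1.06, camera adjusted p = 9.36e-06; adjusted p = 0.256 with an estimated correlation). It had less of glycolysis, 15 of 18 over all genes and over the list alone (median -0.49, camera adjusted p = 1.29e-05; adjusted p = 0.47 with an estimated correlation). Interferon-stimulated genes were lower in 23 and higher in 3 of 35, and 23 and 4 when adjusted over the list alone (median -0.66, camera adjusted p = 0.000414; adjusted p = 0.66 with an estimated correlation). MMP1, the interstitial collagenase, fell by 2.73 (SE 0.16, adjusted p = 4.52e-08), and TNC, the matrix protein tenascin C, fell by 2.69 (SE 0.16, adjusted p = 4.65e-08). In all 8196 genes passed, 3990 higher and 4206 lower. At 2-fold or more there were 1703, and with the dates as blocks 8958.

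**Figure D3:**
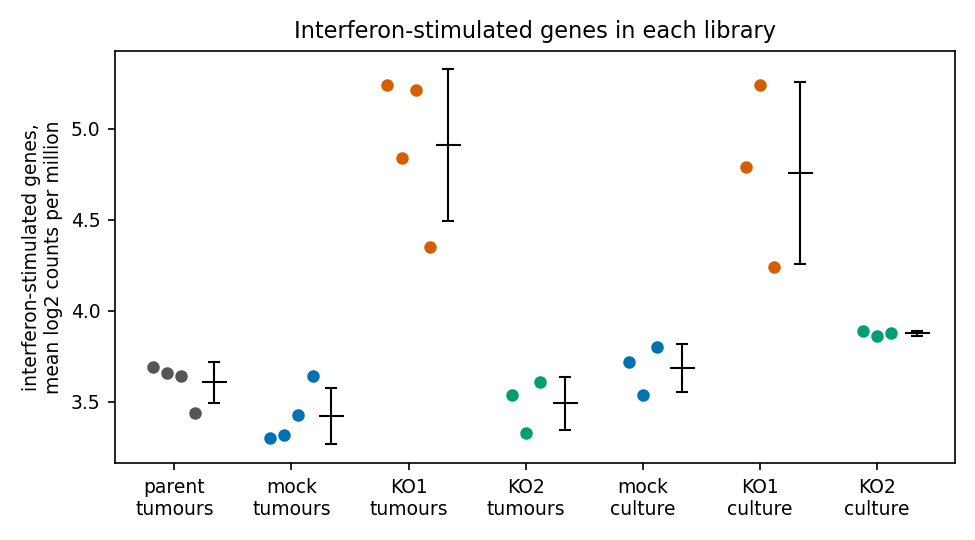
Mean log2 CPM of the interferon-stimulated genes on the vertical axis for each library, with groups on the horizontal axis, points for libraries and bars for the mean with 1 SD. KO1 tumours lie between 4.35 and 5.24 and other tumours between 3.30 and 3.69, while KO1 cultures lie between 4.24 and 5.24, KO2 cultures between 3.86 and 3.89 and mock cultures between 3.54 and 3.80.

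Genes next to MSLN on chromosome 16 were lower in KO2 on the side towards the chromosome end. In cultured KO2 33 of 37 tested genes from that end up to MSLN lay below mock, with a median log2 fold change of -0.68 and 27 past the test, among them STUB1 (-0.80), while the 37 genes beyond MSLN had a median of 0.44 with 24 higher past the test. In KO2 tumours the medians were -0.81 and 0.25 against mock and -0.77 and 0.29 against parent. In KO1 the cultured medians were -0.22 and -0.17. KO1 tumours had medians of -0.25 and -0.28 against mock, with 33 of 36 and 28 of 37 genes lower and 0 and 1 past the test, and of -0.25 and -0.17 against parent, with 0 and 7 lower past the test. These values were computed after the lower neighbours had been seen.

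**Figure D4:**
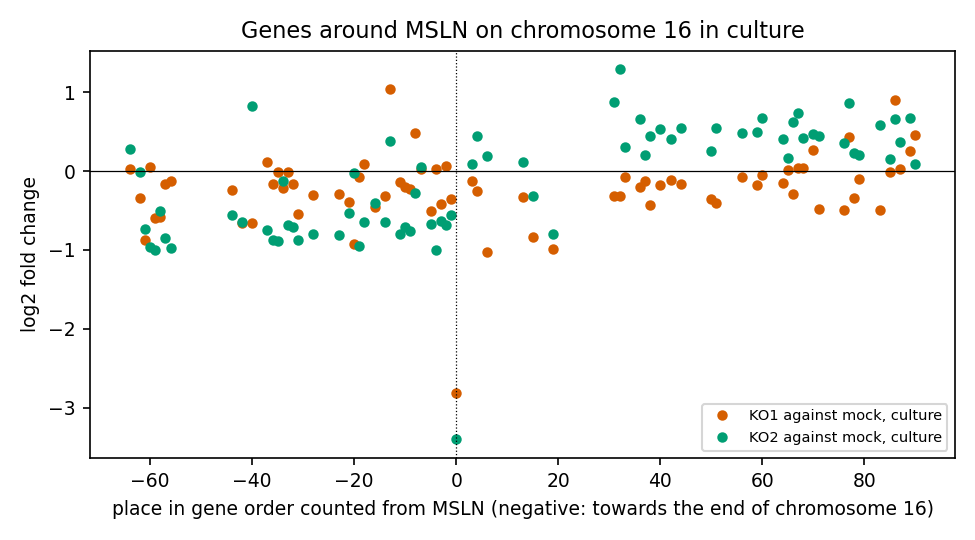
Log2 fold change in culture against mock on the vertical axis, with gene order on chromosome 16 counted from MSLN on the horizontal axis and negative places towards the chromosome end, for KO1 and KO2. KO2 points lie mostly below 0 on the end side, with a median of -0.68, and mostly above 0 beyond MSLN, with a median of 0.44.

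Blocks of neighbouring genes differed from mock in both clones, in culture and in tumours. Of 302 windows of 50 tested genes 24 in KO1 had a median past every window of 100 shuffled gene orders, and all 24 had the same sign in tumours. In KO2 there were 20 such windows, 19 of them with the same sign in tumours. Mock is the control at both sites, so a block can also be mock's own. The window from FAM110C to E2F6 on chromosome 2 was at 0.39 in cultured KO1 and 0.35 in cultured KO2. Against parent tumours it was at -0.04 and -0.11, with parent against mock at 0.31. The lowest in KO1 ran from CXorf38 to PQBP1 on chromosome X (-1.12 in culture and -1.06 in tumours) and held RBM3, TIMP1 and EBP. In KO2 windows on chromosome 17 from TLK2P1 to EZH1, which hold ERBB2, KRT10 and KRT19, were at 0.60 and 0.56 in culture and 0.50 and 0.45 in tumours. Against parent tumours they were at 0.25 and 0.48. Of the 126 genes lower in KO1 than mock tumours 47 lay in the lower windows (37.3%, where 4.37% of tested genes lie), and of the 176 higher ones 7 lay in the higher windows (3.98% against 1.84%). Of the 35 genes lower in KO2 than mock tumours 12 lay in the lower windows (34.3% against 3.91%), and of the 43 genes higher in KO2 than mock tumours 13 lay in the higher windows (30.2% against 1.34%).

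**Figure D5:**
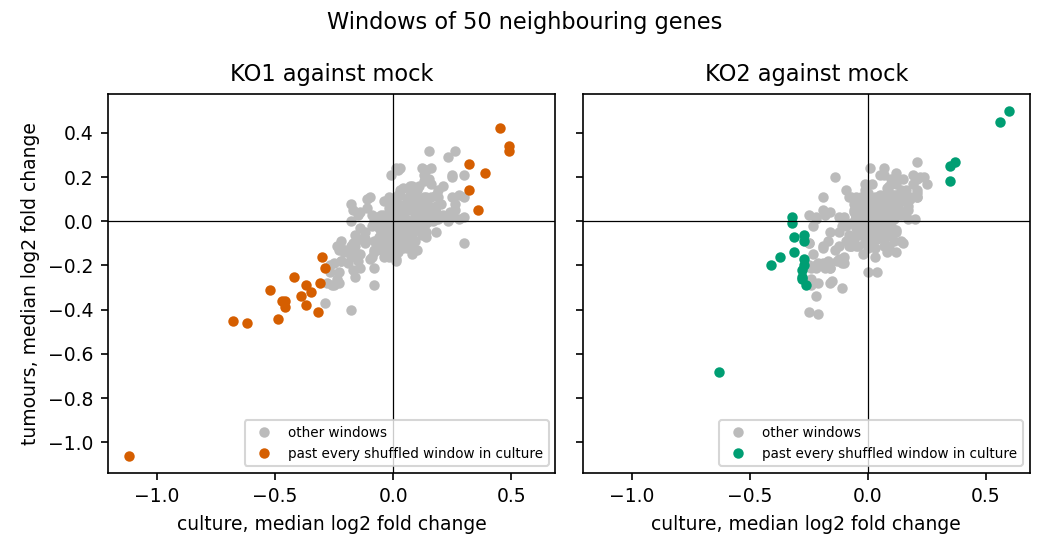
Median log2 fold change of windows of 50 neighbouring genes in culture on the horizontal axis and in tumours on the vertical axis, against mock, for KO1 and KO2. Coloured windows lie past every shuffled window in culture, 24 in KO1 and 20 in KO2, and all but 1 have the same sign in tumours.

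The comparison of tumours with culture over mock, KO1 and KO2 asked how tumour samples from the abdominal cavity differ from cells in the dish. Tumour samples can hold host cells, and human and mouse transcripts were not separated. The values below therefore cannot tell a change within the cancer cells from the share of host cells. Fibroblast, macrophage, mesenchymal and basal-like subtype lists were higher in tumours, and proliferation genes, YAP and TEAD targets and immediate early genes were lower, by camera at the preset correlation. With an estimated correlation only the fibroblast call remained among these. COL3A1, a fibrillar collagen, was 564 to 2950 CPM in tumours and at most 0.401 in culture, and COL1A2 was at least 24800-fold higher, since cultured KO2 had no counts (limit of 3 counts over the group). KRT6A, a keratin of stressed skin, rose by 8.06 (SE 0.43, adjusted p = 3.74e-12). VIM, an intermediate filament of mesenchymal cells, rose by 6.84 (SE 0.18, adjusted p = 1.97e-16), and MMP9, a gelatinase, rose by 4.84 (SE 0.24, adjusted p = 1.46e-12). SLC7A11, the cystine transporter, fell by 4.67 (SE 0.16, adjusted p = 1.19e-14). SPP1, the matrix protein osteopontin, fell by 4.90 (SE 0.21, adjusted p = 1.4e-13), and EGR1, an early response transcription factor, fell by 4.27 (SE 0.19, adjusted p = 2.56e-13).

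All 18 fibroblast markers and all 16 macrophage markers rose, over all genes and over the lists alone (fibroblast markers, median 6.29 and camera adjusted p = 1.45e-31; adjusted p = 0.00446 with an estimated correlation; macrophage markers, camera adjusted p = 6.35e-10; adjusted p = 0.0768 with an estimated correlation). Of the mesenchymal genes 19 of 23 rose and 2 fell, over all genes and over the list alone (median 2.35, camera adjusted p = 2.89e-10; adjusted p = 0.0768 with an estimated correlation). Of the basal-like subtype genes 21 of 29 rose and 7 fell, likewise over the list alone (median 2.47, camera adjusted p = 0.00193; adjusted p = 0.315 with an estimated correlation). Hypoxia response genes rose in 22 of 33 and fell in 5, likewise over the list alone (median 0.69, camera adjusted p = 0.00966; adjusted p = 0.555 with an estimated correlation). NDRG1 rose by 3.41 and EGLN3 by 4.46. Proliferation genes fell in 29 of 36, and 30 when adjusted over the list alone (median -0.84, camera adjusted p = 1.7e-08; adjusted p = 0.343 with an estimated correlation). MKI67, the marker of dividing cells, fell by 1.29. YAP and TEAD targets fell in 18 of 22 and rose in 1, likewise over the list alone (median -1.28, camera adjusted p = 6.87e-08; adjusted p = 0.153 with an estimated correlation). Immediate early genes fell in 14 of 18 and rose in 2, likewise over the list alone (median -1.31, camera adjusted p = 3.01e-06; adjusted p = 0.192 with an estimated correlation). The unfolded protein response list fell in 14 of 23 and rose in 3, and 13 and 3 when adjusted over the list alone (median -0.28, camera adjusted p = 0.00122; adjusted p = 0.315 with an estimated correlation), among them ASNS (-2.83), which makes asparagine, and CHAC1 (-3.24), which degrades glutathione.

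Of the angiogenic factors 16 of 26 rose and 6 fell between culture and tumours, likewise over the list alone (median 0.86, camera adjusted p = 0.0472; adjusted p = 0.315 with an estimated correlation), with PGF at 3.26. That call was lost without KO2 tumour 4 (adjusted p = 0.119) or KO2 culture 1 (adjusted p = 0.05). VEGFA fell by 0.78 (SE 0.17, adjusted p = 0.000306), with a sign that turned to 0.13 with the muscle and acinar scores as covariates. These scores are lower in every culture than in every tumour, so that fit cannot tell them from the site. In all 14698 of 18994 genes passed, 7993 higher and 6705 lower, and tumours and cultures stand in separate tables with different depths, so site and table cannot be told apart. At 2-fold or more there were 7206 genes, with the muscle and acinar scores 3213, with a stricter filter 7830 and among genes expressed in culture 7591.

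The last comparison asked whether the knockout difference itself differed between tumours and culture. It passed for 27 of 18994 genes, 22 with a higher and 5 with a lower difference in tumours, and in most named ones the knockout effect was in culture. BMP7 was 0.33 in tumours and -1.46 in culture (difference 1.78, SE 0.27, adjusted p = 0.00482), and APCDD1 was 0.68 and -2.62 (difference 3.31, SE 0.47, adjusted p = 0.00332). SPINK5 was higher in knockout tumours (1.58) and lower in knockout cultures (-1.13, adjusted p = 0.0557), a difference of 2.72 (SE 0.40, adjusted p = 0.00482). CAPN12, a calpain protease, was 0.36 in tumours and 2.14 in culture (difference -1.78, SE 0.23, adjusted p = 0.00135). The difference for ICAM1 was -0.81 (SE 0.17, adjusted p = 0.0572). NF-kB targets had a median difference of -0.43 with none past the test over all genes and 3 lower when adjusted over the list alone (camera adjusted p = 9.88e-06; adjusted p = 0.222 with an estimated correlation), and 1 lower over all genes without mock tumour 4 or KO2 tumour 2 or 4. The interferon-stimulated genes had one of 0.15 with none past either test (camera adjusted p = 0.295). Camera called 9 of 39 lists here, and 0 with an estimated correlation. Hypoxia response (median -0.36) and glycolysis (median -0.33) had the same camera adjusted p as the NF-kB targets. Also called were the unfolded protein response (-0.29, camera adjusted p = 0.000753), MHC class I antigen presentation (-0.33, camera adjusted p = 0.00178) and WNT targets (0.48, camera adjusted p = 0.00183). With the muscle and acinar scores as covariates edgeR called 0, with 1015 at an unadjusted p under 0.05, while DESeq2 without them called 166. Other regroupings of the same libraries gave more, and leaving out mock tumour 3 or 4, KO2 tumour 2 or mock culture 1 or 3 gave 17, 61, 60, 12 and 16.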

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

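The tests of muscle and acinar tissue and line differences, of the lost end of chromosome 16, of MSLN reads on that end, of copy number and of other pairings of the lines were chosen only after the result was seen.

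Muscle markers were high in 8 tumours and acinar markers in 7, and low in every culture of the same cells. Of the muscle markers 12 of 13 had an r of at least 0.5 against the other members and of the acinar markers 15 of 16, a lower share of 92.3%, which is consistent with muscle and pancreas tissue in the tumour samples. A difference between the lines is excluded as the sole source for muscle, since tumours of 3 lines span over 50% of the whole range. For acinar markers the tumours of 1 line do so, the parent, while all KO1 tumours are high and all mock and KO2 tumours low, so tissue and line stay open. Whether site of growth in the animal or dissection differed between the lines was not tested.

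In KO2 33 of 36 genes between the end of chromosome 16 and MSLN were lower in tumours than in both mock and parent (91.7%), while genes beyond MSLN were not, and in KO1 tumours 33 of 36 lay below mock by less (median -0.25 against -0.81 in KO2), as did 28 of 37 beyond MSLN. Loss of 1 copy of that end is a candidate explanation, as a hypothesis without DNA data, and copy number differences between the clones could also account for the other blocks, of which at least 95% in each clone kept their sign in tumours. Reads of MSLN counted on its neighbours are excluded, with 25 genes more than 2 places away called lower in cultured KO2, and with 2 such members of the neighbour list called lower in both clones. A loss on both sides of MSLN in both clones is excluded by the culture values, since the higher median over the 50 nearest genes was 0.06, in KO2 against mock. In KO2 tumours that median was -0.28 against mock and -0.67 against parent, and in KO1 tumours -0.23 against each. The genes beyond MSLN alone had medians of 0.25 and 0.29 in KO2 tumours against mock and parent. A high level in mock alone is excluded for KO2, whose list median against parent was -0.68, and stays open for KO1 at -0.22.

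Only 2 genes were called in all 4 tumour line pairs. Other pairings of the lines gave 4 and 26. The 26, for KO1 and parent against KO2 and mock, hold many digestive enzyme genes, among them AMY2B, CELA1 and CTRB2. That pairing largely follows the acinar markers, whose source stays open. Differences between the lines other than MSLN, or in acinar tissue, may account for much of what separates single pairs. Host tissue hiding shared genes stays open, since the fit with the muscle and acinar scores gave 0 but also lost MSLN in KO1 against mock (-2.68, SE 0.56, adjusted p = 0.577). Too few tumours stays open, since 74% of simulated genes with a 4-fold change in both knockout lines were called in all 4 pairs and 14% of those with a 2-fold change. A small shared effect of MSLN loss was not tested beyond this.

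Libraries were regrouped at random to count calls without the real groups. For KO1 against mock tumours 1 of 35 splits, the real one, reached 302 calls, with 0 at most in the others. For KO2 against mock it was 1 of 35 with 78 calls and 7 at most in the others, and for parent against mock 1 of 35 with 541 and 151 at most. Random assignment of single libraries is excluded for these at that number of splits. The splits cannot exclude differences in host tissue between the tumours. For KO2 against KO1 tumours 3 of 35 splits reached 546 calls, the highest at 1414 with KO1 tumour 4 grouped with KO2 tumours 3 and 4, and chance is not excluded. For knockout against MSLN-expressing tumours it was 1 of 100 with 177 calls and 20 at most in the others, but pairing whole lines the other 2 ways gave 360 and 742, so lines paired in any way exceeded the random groups. For the genes called in all 4 pairs it was 1 of 100 with 2 and 0, and for tumours against culture 1 of 100 with 14698 and 8395. For cultured knockout lines against mock 2 of 100 reached 3527 calls, the other at 5319 with KO1 cultures as the lone line, so that value follows the lines. The cultured single lines had 10 splits each, with 1 of them, the real one, reaching 6070, 4014 and 8196 calls, which are too few splits. For the difference between sites 7 of 100 reached 27 calls, the highest at 152, and chance is not excluded.

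Of 85 groups of 4 tested for a library far from the rest 6 had one, where chance flags about 1 in 20 groups. The score of mitochondrial transcripts was 11.69 in parent tumour 1 (next 11.23), and the muscle score 8.38 in parent tumour 4 (next 0.68). ICAM1 was 8.39 CPM in parent tumour 4 (next 15.2), VIM 664 CPM in mock tumour 4 (next 503) and MMP7 31.8 CPM in mock tumour 2 (next 8.50). KO2 tumour 1 had 2.22 M counts (next 10.61 M). Its ACTA1 count was 18513, against 8 at most in culture and 5841 at least in the other KO2 tumours, so muscle transcripts were present in it too.

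The knockout difference was higher in tumours than in culture for INSR (1.84), SPINK5 (2.72), OLFML3 (1.90), SUSD4 (1.88), BCL11A (1.66), HCLS1 (1.56), BMP7 (1.78) and APCDD1 (3.31). It was lower for CAMK2N1 (-0.89), PTPRH (-1.12), NANOS1 (-1.38) and CAPN12 (-1.78). These values pool both clones and can come through 1 of them. For HCLS1 the pooled culture value was -1.62, while the fall in cultured KO1 given above was larger. Chance is not excluded for this comparison, as stated for the regrouped libraries.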

How the results depend on the processing

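All alternatives but 6 were chosen before the data were examined. Added after seeing the data were KO2 tumour 1 included, the muscle and acinar scores as covariates, culture-expressed genes only, genes of chromosomes 1 and 2 alone, gene lists with each library left out, and gene lists without MSLN as a member. The cause of the shifts was not tested unless given here.

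Counts are given in the order knockout tumours, genes in all 4 pairs, KO1 against mock, KO2 against mock, parent against mock and KO2 against KO1. DESeq2 gave 626, 8, 787, 331, 1415 and 1159, and 166 for the difference between sites. The stricter filter gave 110, 1, 157, 50, 271 and 356, then 7830 for tumours against culture and 14 for the difference between sites. Culture-expressed genes only gave 91, 1, 166, 41, 225 and 337, then 7591 and 6. The cell content score as a covariate gave 3, 1, 190 and 46, and 9 for parent against mock.

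The muscle and acinar scores as covariates gave 66, 0, 0, 61, 1 and 0, then 3213 for tumours against culture and 0 for the difference between sites. KO2 tumour 1 included gave 0, 0, 1, 0, 0 and 12, then 7255 and 0, and MSLN in knockout tumours had an adjusted p = 0.468. That library has no counts for most genes, which by construction widens the spread within KO2. On genes of chromosomes 1 and 2 alone it raised the count from 24 to 39 for knockout tumours, from 15 to 31 for KO2 against mock and from 75 to 131 for KO2 against KO1.

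A 2-fold minimum, which can only remove genes, gave 82 for knockout tumours, 345 for KO2 against KO1 tumours, 398, 1051, 620 and 1703 in culture (both clones, KO1, KO2, KO2 against KO1) and 7206 for tumours against culture. Only the 2 groups compared gave 175, 2 and 160 for KO1 against mock, KO2 against mock and KO2 against KO1 tumours. The parent as control gave 791 and 488 for KO1 and KO2. No filter gave 85 for the difference between sites. The culture dates as a replicate block gave 4577, 6963, 4974 and 8958 in culture. Same-date libraries had r from -0.05 to 0.25 over 9 pairs and other pairs -0.30 to 0.15 over 18, so the dates could pair some of the cultures but not all.

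With 1 library left out the counts ran from 66 to 199 for knockout tumours, 1 to 3 for genes in all 4 pairs, 141 to 321 for KO1 against mock, 17 to 135 for KO2 against mock, 86 to 855 for parent against mock and 240 to 637 for KO2 against KO1 tumours. In culture they ran from 2126 to 4016 for both clones, 4604 to 5965 for KO1, 2742 to 4269 for KO2 and 6844 to 8187 for KO2 against KO1. Tumours against culture ran from 14406 to 15293 and the difference between sites from 12 to 61. Gene list calls by camera at the preset correlation were kept in 1607 of these tests and lost in 144.

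Among named genes and lists called in either fit, signs of the test reversed only with the muscle and acinar scores as covariates. With 1 library left out the test direction of lists not called either way changed in 194 tests, among them mitochondrial transcripts in cultured KO1 without mock culture 3 (median -0.10). Medians of called lists changed sign for hypoxia response in KO2 against mock tumours (-0.17, and 0.06 without KO2 tumour 2), mucins in KO2 against KO1 cultures (0.08, and -0.02 without KO1 culture 1) and mesothelial markers, which hold MSLN, in 3 comparisons. CELA1 turned to -0.17 in KO1 against mock, -0.11 in parent against mock and 0.28 in KO2 against KO1 tumours, and AMY2B to 0.08 in the last, which the acinar score holds by construction. In tumours against culture ATP2A1 turned to -1.16, VEGFA to 0.13, MT-ND2 to 0.05 and MT-ND4L to 0.87. The muscle score was at most -1.52 in culture and at least 0.38 in mock, KO1 and KO2 tumours. Score and site therefore overlap, and that fit cannot tell them apart. Lists that reversed in KO1 against mock were mesenchymal genes (adjusted p = 0.0355), proliferation (adjusted p = 6.79e-08), immediate early genes (adjusted p = 0.0355) and muscle markers (adjusted p = 0.789). Hypoxia response reversed in parent against mock (adjusted p = 0.0487), mucins (adjusted p = 0.877), fibroblast markers (adjusted p = 0.000601) and muscle markers (adjusted p = 0.739) in KO2 against KO1, and oxidative phosphorylation in KO2 against parent tumours (adjusted p = 0.00861). The acinar score was 3.59 or more in every KO1 tumour and -1.39 or less in every mock and KO2 tumour. In KO1 against mock and KO2 against KO1 the fit therefore cannot tell the score from the line.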

Other observations

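Cultured KO1 and KO2 cells moved away from mock in opposite ways in MAPK pathway output and glycolysis genes. Of 18 genes of MAPK pathway output 10 rose and 1 fell in KO1, and 11 and 1 when adjusted over the list alone (median 0.34, camera adjusted p = 0.00737; adjusted p = 0.51 with an estimated correlation). In KO2 1 rose and 9 fell over all genes and over the list alone (median -0.22, camera adjusted p = 0.00123; adjusted p = 0.497 with an estimated correlation), and 5 fell without mock culture 3. Glycolysis genes rose in 8 and fell in 1 of 18 in KO1, and 9 and 1 when adjusted over the list alone (median 0.24, camera adjusted p = 0.00169; adjusted p = 0.51 with an estimated correlation). In KO2 they rose in 1 and fell in 7, and 1 and 8 when adjusted over the list alone (median -0.27, camera adjusted p = 0.0187; adjusted p = 0.729 with an estimated correlation), and that call was lost without KO2 culture 2 (adjusted p = 0.0627), KO2 culture 3 (adjusted p = 0.0615) or mock culture 1 (adjusted p = 0.0519). In tumours glycolysis genes were lower than in mock in both clones. The median was -0.34 in KO1 (camera adjusted p = 0.00024) and -0.29 in KO2 (camera adjusted p = 0.000194). The KO1 call was lost with an estimated correlation. Against parent only KO2 was called (median -0.24, camera adjusted p = 0.0424), and not in 4 of 7 fits with a library left out. MAPK pathway output was lower than in mock in KO2 tumours (median -0.29, camera adjusted p = 0.000442) and not called in KO1.

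Cultured KO2 cells had more mitochondrial transcripts and less of the nuclear genes of oxidative phosphorylation. Transcripts of the mitochondrial genome rose in 12 of 13 over all genes and over the list alone (median 0.63, camera adjusted p = 6.77e-06; adjusted p = 0.497 with an estimated correlation). Without mock culture 3 the median was 0.43 with 6 higher (adjusted p = 3.11e-05), and without KO2 culture 1 it was 0.42 with 6 higher (adjusted p = 0.000432). Nuclear genes of oxidative phosphorylation fell in 9 of 27, and 12 when adjusted over the list alone (median -0.18, camera adjusted p = 5.78e-05; adjusted p = 0.497 with an estimated correlation). Histone genes fell in 2 of 10 in KO2 against KO1 tumours, and 7 when adjusted over the list alone (median -0.58, camera adjusted p = 3.2e-05, or adjusted p = 0.0544 with an estimated correlation). The 2 became 1 without KO1 tumour 1 or 2 or KO2 tumour 2 or 4 and 0 without KO2 tumour 3. Histone genes were also higher than in mock tumours in KO1 (median 0.68, camera adjusted p = 1.65e-05) and parent tumours (median 0.65, adjusted p = 0.000133), as were the acinar markers.

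Genes shared by the cultured knockout clones were followed into tumours after the culture result was seen. Of 538 genes higher in both clones and measured in tumours 361 were higher there (67.1%), and of 477 lower genes 344 were lower (72.1%). These genes were chosen against mock, which is also a control in tumours, and 125 and 167 of them kept the sign in all 4 line pairs. In the tumour test 13 and 21 of them passed the same way and 4 and 1 the other way. Of those with a 2-fold change in each clone 48 of 63 higher genes were higher in tumours (76.2%, median 0.40), and 34 of 61 lower genes were lower (55.7%, median -0.05 in tumours against -1.47 in culture). Over all 15383 genes measured at both sites 59% had the same sign, and no test was made of these shares.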
